A study of Mus musculus with 17 samples.

How the data were processed

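Total RNA of whole mouse hearts was sequenced in 17 libraries from 2 genotypes, WT and a line labelled bsg, with both sexes in each. Per the labels' protocols the mice were 4 months old, the hearts were flash frozen, RNA was isolated with a silica-column kit, and stranded libraries were prepared after depletion of ribosomal RNA. The samples were grouped by the genotype and sex in the labels, which gave 4 WT females, 3 WT males, 5 bsg females and 5 bsg males. The series' design text gives 3 to 4 animals per group, so the 5 libraries in each bsg group are more than it states. The design text calls them biological replicates. Some titles of one group share a number whose meaning is not stated. Each title also ends in an S number, whose meaning is not stated either and which no test used. Every WT female had a higher S number than every bsg male, so this number is uneven across the groups. No sequencing batch or date was given in the sources used here.

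The deposited table holds raw fragment counts per gene, which the authors had not normalized. Per the file headers the counts were made with featureCounts 1.6.2 from paired fragments with both ends aligned, a minimum mapping quality of 10, the reverse-strand setting 2 and the Ensembl release 109 annotation of the assembly C57BL_6NJ_v1. The submitters' processing notes name featureCounts, Subread, DESeq2 and the build GRCm39, whereas the coordinates in the table belong to C57BL_6NJ_v1, and the file's coordinates on that assembly are used throughout. The aligner's settings are not given in the sources used here. The table lists 41096 genes on 20 chromosomes, 1 to 19 and X. It lists 0 genes on chromosome Y and 0 on the mitochondrial genome, so neither was analysed here. No gene ID was listed more than once and no column was left unused. Because strand was used in counting, overlapping genes on opposite strands were counted apart, while overlapping genes on the same strand and near-identical copies remain uncertain. A minimum mapping quality of 10 removes fragments that align equally well to several places, which lowers the counts of genes with close copies.

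The table does not pair its IDs with gene names. Of its 41096 IDs, 0 matched the ID tables used here, which cover another assembly. Genes are therefore given by ID and position, with at most 2 that were higher and 2 that were lower in each comparison. The 42 gene lists and marker lists fixed before the data were examined hold symbols and could not be applied. The antioxidant genes that the series title refers to, the gene that the bsg label stands for and markers of other cell types could therefore not be identified among the tested genes. Whether any of them is among the genes called between bsg and WT was not determined. No reference sequence of this assembly was used here.

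Genes with too few counts were removed with edgeR's filterByExpr at its default settings (minimum count 10, minimum total count 15), which left 15013 genes. Counts were scaled by the TMM method, and a quasi-likelihood negative binomial model with 1 mean per group was fitted to all 17 libraries in edgeR 4.0.16 under R 4.3.3, so that the 4 groups shared 1 estimate of the spread. The 5 comparisons were bsg against WT in males, bsg against WT in females, males against females in WT, males against females in bsg, and the interaction of sex and genotype. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. Levels are given as CPM, the counts relative to the TMM-scaled library total, as mean and SD over the libraries of a group, and log2 fold changes with a standard error (SE). The SE was derived from the test, as the absolute log2 fold change over the square root of its F statistic. It is not a separate model estimate and can be too small where a group is near 0 counts. Where a group had no count, the fold was set against a floor of 3 counts per library. Intervals and floors from counts are at a level of 95 percent and cover counting error only.

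To describe where called genes lay, tested genes were assigned by their start to 10 Mb bins, 286 in all, and the calls in each bin were compared with an exact hypergeometric test, one-sided and adjusted over the bins. The binning was chosen after the data were examined. Genes to be named were chosen by a rule fixed before the data were examined: among called genes with an average log2 CPM of at least 1, those with the largest changes each way. The part of the rule that needs symbols could not be applied. The rule asked for more genes each way than the 2 given here, so it was shortened. Where no gene was called in the interaction, those with the smallest p are given as not passing. They are given for each direction apart, where the rule took both directions together.

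Alternatives were RLE and upper-quartile scaling, no filter or a filter of CPM above 1 in at least 3 libraries, DESeq2 1.42.0, limma-voom 3.58.1 without and with the title number as a random block or with library weights, a fold of at least 1.5, an adjusted p under 0.01, fits of the 2 compared groups only, libraries summed by title number, removal of X genes, and leaving out each library in turn. Fits without 2 or 3 libraries that lie apart on the first principal component were added after the data were examined. Replicate libraries of 1 group were compared pair by pair. The chi-square over its degrees of freedom ranged from 5.29 to 36.3 over the 29 pairs, so no pair differed by as little as sampling noise.

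The procedure was tested on simulated counts for the same 15013 genes with the means, library sizes and dispersions of the real libraries, with 200 genes changed. Genes were drawn independently, without the spread that libraries share across genes, such as that along the first principal component. Fewer changed genes make the adjusted threshold stricter, so recovery would be lower in a comparison with fewer true changes. Of genes changed 2-fold, the test recovered 76.1% for bsg against WT in males, 70.1% for the same comparison in females, 68.7% for the sexes in WT, 77.6% for the sexes in bsg and 64.2% for the interaction. Of genes changed 1.5-fold it recovered 49.3%, 59.7%, 65.7%, 59.7% and 32.8% in the same order. False calls numbered 8, 11, 10, 7 and 5. Total counts ranged from 13886399 to 17554850 per library, at which a single count corresponds to 0.0543 to 0.0739 CPM.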

Results

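Gene expression was measured by RNA sequencing of whole hearts from 17 mice aged 4 months. The mice were wild type (WT, 4 females and 3 males) or carried the genotype labelled bsg (5 females and 5 males), which the series title places in a study of genetic cardiomyopathy in males. Each library held between 13886399 and 17554850 fragments assigned to genes, with a median of 15736903. Between 18597 and 20589 genes had at least 1 count, and the 10 most abundant genes took 10.99% to 12.54% of a library. The table lists genes by the IDs and coordinates of the C57BL_6NJ_v1 assembly without names, so genes are described by ID and place.

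The second principal component of log2 CPM (11% of the variance) followed genotype, with scores of 3.35 to 27.02 in the 7 WT hearts and -19.13 to -3.51 in the 10 bsg hearts. The first component (37.4%) followed neither genotype nor sex. Its highest scores were those of bsg female replicate 2 (74.9), WT female replicate 2 (51.8) and WT male replicate 2 (29.0), while the other 14 libraries had scores from -31.4 to 14.4. The S numbers in the titles of these 3 libraries are among the highest. So is that of bsg female replicate 1, which scored -10.2. Whether the first component followed the S number was not tested.

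**Figure D1:**
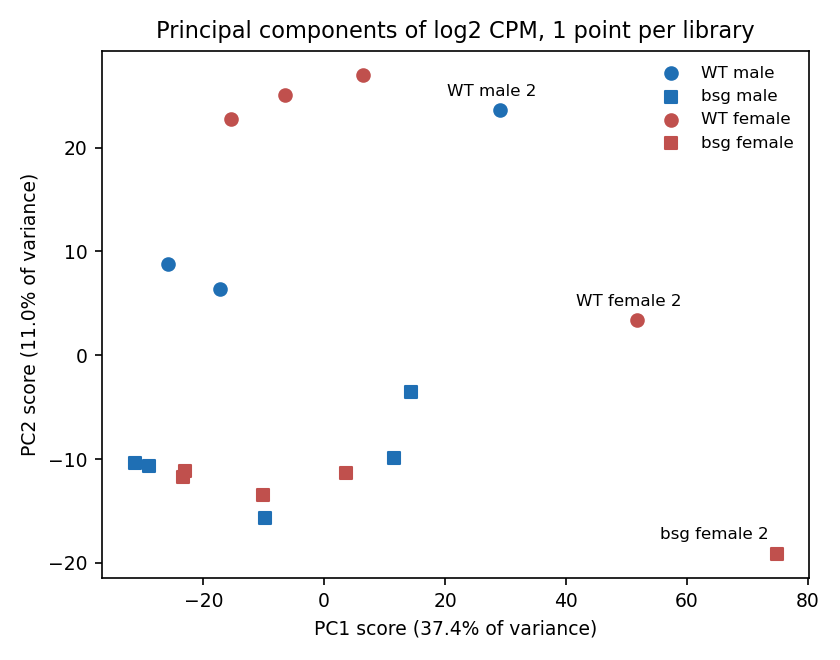
Scores of the 17 libraries on the first and second principal components of log2 CPM (arbitrary units), 1 point per library, with circles for WT, squares for bsg, blue for males and red for females. WT libraries lie at 3.35 or above on the second component and bsg libraries at -3.51 or below, and the 3 libraries with the highest scores on the first component are named.

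The first comparison asked which cardiac genes differed between bsg and WT males. The largest fall was on chromosome 5, where MGP_C57BL6NJ_G0030059 (76681878 to 76696974, minus strand, exonic length 4052 bp) stood at 215 ± 13.2 CPM in WT males (SD, n = 3) and 5.47 ± 0.649 CPM in bsg males (SD, n = 5). This was a log2 fold change of -5.29 (SE 0.10, adjusted p = 1.26e-15 by edgeR), or 39.2-fold lower. Its neighbour on the same strand, MGP_C57BL6NJ_G0030058 (76655452 to 76681655, exonic length 3238 bp), begins 222 bp away and rose. It had 2 counts in all over the 3 WT males and 34.4 ± 2.66 CPM in the 5 bsg males, a ratio of 799 with an exact Poisson interval of 221 to 6600 and an adjusted p of 5.68e-11 by edgeR. MGP_C57BL6NJ_G0025562 on chromosome 19 (43154332 to 43181246, minus strand, exonic length 3119 bp) rose from 1.29 ± 0.186 to 14.7 ± 1.40 CPM, a log2 fold change of 3.50 (SE 0.20, adjusted p = 2.86e-08). MGP_C57BL6NJ_G0028704 on chromosome 4 (49747444 to 49762423, minus strand, exonic length 2392 bp) fell from 18.8 ± 5.73 to 1.06 ± 0.370 CPM, a log2 fold change of -4.12 (SE 0.29, adjusted p = 1.79e-07). For each of these 4 genes, the ranges of the bsg and WT libraries did not overlap.

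In all, 82 of 15013 genes were called in males, 44 higher and 38 lower in bsg. At least 2-fold changes made up 32 of them, 16 in each direction. The calls were concentrated on a few chromosomes. Chromosomes 2, 5 and 19, which held 17.8% of the tested genes, held 45 of the 82 calls, and each of them had more calls than the rest of the genome by Fisher's exact test (one-sided adjusted p = 9.56e-05, 0.00217 and 0.00259). Within them, the stretch of chromosome 2 from 170 to 180 Mb held 14 called genes of 98 tested (adjusted p = 4.26e-14, exact hypergeometric test). Chromosome 5 held 5 of 40 between 70 and 80 Mb and 4 of 49 between 90 and 100 Mb, and chromosome 19 held 5 of 49 between 30 and 40 Mb (adjusted p = 0.000348, 0.0104 and 0.000647, same exact test). The count of calls fell to 49, 44 and 39 without WT male replicate 1, 2 or 3 and to 38 with libraries summed by title number, rose to 232 by DESeq2, and was 109 without the WT and bsg female replicates 2. The balance of directions was not stable: it was 37 higher and 39 lower with upper-quartile scaling, 104 and 127 with library weights, 54 and 55 without the WT and bsg female replicates 2, and 37 and 46 without WT male replicate 2 as well.

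**Figure D2:**
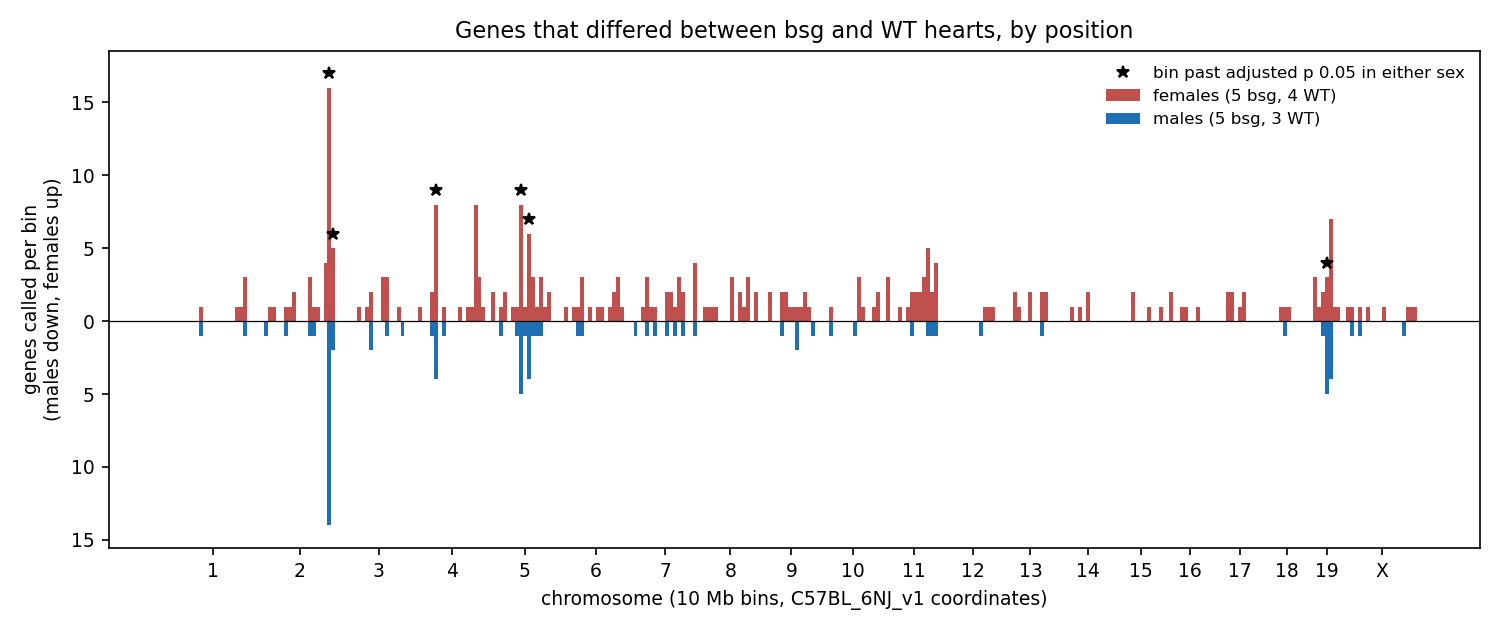
Number of genes called between bsg and WT hearts in each 10 Mb bin along chromosomes 1 to 19 and X, with females drawn upward and males downward, and stars on the 6 bins with more calls than expected in either sex. The tallest bar in both sexes is chromosome 2 from 170 to 180 Mb, with 14 calls in males and 16 in females.

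The same question was asked in females. The neighbouring pair on chromosome 5 again gave the largest rise and the largest fall by the rule for named genes. MGP_C57BL6NJ_G0030059 fell from 228 ± 15.3 CPM in WT (SD, n = 4) to 4.93 ± 0.778 CPM in bsg (SD, n = 5), a log2 fold change of -5.54 (SE 0.10, adjusted p = 4.72e-16 by edgeR). MGP_C57BL6NJ_G0030058 had a count of 0 in each of the 4 WT females and 33.8 ± 4.29 CPM in the 5 bsg females. Set against 3 counts per library, this was at least 175-fold higher (adjusted p = 8.02e-12 by edgeR). MGP_C57BL6NJ_G0012235 on chromosome 2 (177159089 to 177159584, minus strand, a single exon of 496 bp) rose from 1.68 ± 0.647 to 21.1 ± 2.52 CPM, a log2 fold change of 3.64 (SE 0.21, adjusted p = 2.01e-08). MGP_C57BL6NJ_G0030950 on chromosome 6 (27615813 to 27629766, plus strand, exonic length 3354 bp) fell from 7.03 ± 4.00 to 0.322 ± 0.373 CPM, a log2 fold change of -4.42 (SE 1.08, adjusted p = 0.0465). That last call was narrow: over the alternatives its log2 fold change stayed between -5.34 and -4.05, and it missed the threshold in 13 of 21.

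A total of 270 genes were called in females, 150 higher and 120 lower in bsg, of which 50 changed at least 2-fold (27 higher and 23 lower). A larger part of the calls were small changes than in males, with 172 of the 270 under 1.5-fold. Chromosomes 2, 5 and 19 held 86 of the calls (adjusted p = 0.0158, 0.0133 and 0.0284, one-sided Fisher's exact test). The bin of chromosome 2 from 170 to 180 Mb held 16 called genes of 98, and the next one, to 190 Mb, 5 of 35 (adjusted p = 5.57e-09 and 0.0271, exact hypergeometric test). On chromosome 5, 8 of 40 genes were called between 70 and 80 Mb and 6 of 49 between 90 and 100 Mb, and on chromosome 4, 8 of 108 between 40 and 50 Mb (adjusted p = 6.59e-05, 0.0223 and 0.0421, same exact test). The count of calls fell to 126 and 161 without WT female replicate 1 or 3 to 157 and 179 without bsg female replicate 1 or 3 and to 60 with libraries summed by title number, rose to 542 by DESeq2, and was 244 without the WT and bsg female replicates 2. The balance of directions rested on single libraries: without WT female replicate 2 it was 129 higher and 164 lower, and without WT female replicate 4 it was 145 higher and 188 lower. With the 2 compared groups fitted alone, 109 genes were called in females and 151 in males.

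**Figure D3:**
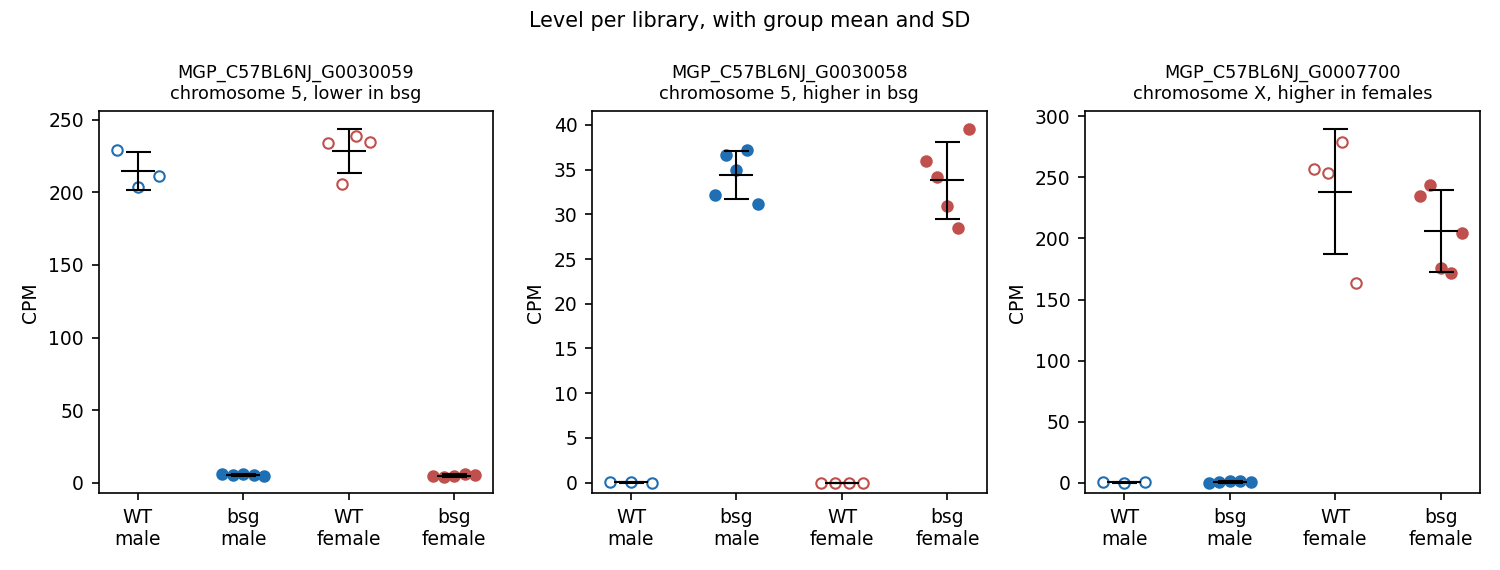
CPM per library of the neighbouring pair of genes on chromosome 5 and of the X-linked gene with the largest sex difference, 1 point per heart, with the group mean and SD as bars and linear axes. WT hearts lie at 203.8 CPM or above and bsg hearts at 6.18 CPM or below for MGP_C57BL6NJ_G0030059, and the pattern is opposite for MGP_C57BL6NJ_G0030058.

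The genotype difference was then compared between the sexes, which share no libraries. Of the 298 genes called in at least 1 sex, 54 were called in both, 29 higher and 25 lower in bsg, against 0.44 and 0.30 for independent lists, and 0 were called in opposite directions. The lists are not fully independent, because the spread of each gene was estimated over both sexes in 1 fit. This can favour the same genes in both lists, so 0.44 and 0.30 may be too low. Of the 270 genes called in females, 260 had the same sign in males, and of the 82 called in males, 79 had the same sign in females. The 6 bins named above for either sex held 379 tested genes (2.5%). They held 34 of the 82 calls in males (17 higher and 17 lower), 46 of the 270 in females (24 higher and 22 lower) and 28 of the 54 shared calls. The bins depended on their width: with 5 Mb bins, 4 passed, on chromosomes 2, 5 and 19, with 23 calls in males and 30 in females, and with 20 Mb bins, 5 passed, on chromosomes 2, 4, 5 and 19, with 31 and 52. The 4 bins found in males held 33 of 236 genes called in females (13.98%), against 1.6% elsewhere (odds ratio 9.97, p = 3.29e-20, one-sided Fisher's exact test). Across genes, which are not independent replicates, Pearson's r of the log2 fold changes in the 2 sexes was 0.332 over all tested genes, 0.866 inside the bins and 0.239 outside, and Spearman's rho over all genes was 0.254. The r over all genes was 0.212 without bsg female replicate 2 and 0.042 without WT male, WT female and bsg female replicates 2, where rho was 0.226. Without those 3 libraries r was 0.765 inside the bins and -0.057 outside, where it was 0.233 without the 2 female libraries only. The called genes still went mostly the same way without those 3 libraries. Of 284 genes called in females, 253 had the same sign in males, and of 83 called in males, 76 had the same sign in females. All 48 genes then called in both sexes had the same sign.

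**Figure D4:**
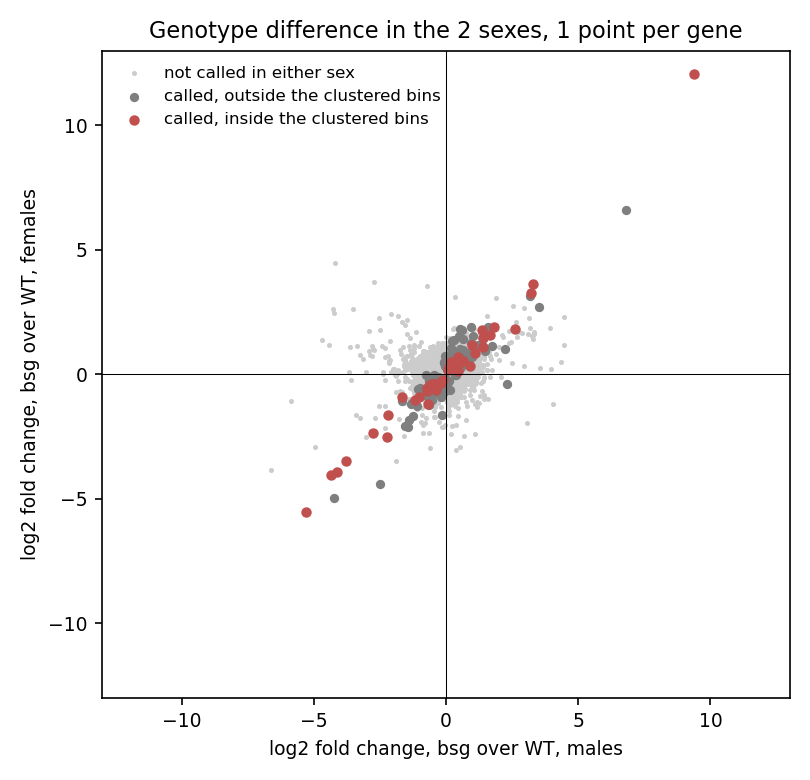
Log2 fold change of bsg over WT in males (horizontal axis) and females (vertical axis), 1 point per tested gene, with genes called in either sex in dark grey (outside the 6 bins) or red (inside). All 52 called genes inside the bins have the same sign in both sexes, as do 233 of the 246 outside.

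The sexes were compared within each genotype. In the main fit of both genotypes the genes higher in females lay on the X chromosome, the same 6 genes each time, of 500 X-linked genes tested. The largest difference was that of MGP_C57BL6NJ_G0007700 (X, 103072506 to 103094731, minus strand, exonic length 17233 bp). It had 238 ± 51.1 CPM in WT females (SD, n = 4) and 206.1 ± 33.1 CPM in bsg females (SD, n = 5), against 0.456 ± 0.513 CPM in WT males (n = 3) and 0.937 ± 0.718 CPM in bsg males (n = 5). Every library labelled female had at least 163.5 CPM of it and every library labelled male at most 1.91, so for this gene each library lay with its labelled sex. The gene was picked by these same labels, so its levels are not an independent check of them. The log2 fold change of males over females was -9.01 (SE 0.51) in WT and -7.76 (SE 0.36) in bsg, with adjusted p of 4.84e-08 and 2.46e-09 by edgeR. In the WT males it rested on 15, 0 and 6 counts. It was -10.2 in WT without WT male replicate 1 and -8.46 without WT male replicate 2. The SE by DESeq2 and by limma-voom was 0.712 and 1.17 in WT, and 0.555 and 0.634 in bsg. The other 5 genes were between 1.52 and 1.82 times higher in WT females and between 1.46 and 1.79 times higher in bsg females. Among them, MGP_C57BL6NJ_G0036090 (X, 13358433 to 13486033, plus strand, exonic length 8196 bp) had 46.6 ± 2.01 CPM in WT females and 25.6 ± 1.77 in WT males, and 46.5 ± 2.55 and 26.0 ± 2.46 CPM in bsg females and males (log2 fold change -0.86 with SE 0.08 in WT, -0.84 with SE 0.06 in bsg).

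The genes higher in males were autosomal, 3 in WT and 8 in bsg, of which 2 were shared. Each of them had a positive log2 fold change of males over females in both genotypes. The groups were smaller in WT (3 males and 4 females) than in bsg (5 males and 5 females). A call in 1 genotype only therefore does not show a difference between the genotypes. MGP_C57BL6NJ_G0022095 on chromosome 15 (1964392 to 2045218, minus strand, exonic length 2709 bp) stood at 27.3 ± 10.7 CPM in WT males and 4.197 ± 0.565 in WT females (log2 fold change 2.70, SE 0.29, adjusted p = 0.000176 by edgeR), and at 20.7 ± 6.49 and 6.08 ± 1.59 CPM in bsg males and females (1.76, SE 0.24, adjusted p = 0.00247). MGP_C57BL6NJ_G0017218 on chromosome 1 (186068896 to 186105573, minus strand, exonic length 3891 bp) stood at 14.4 ± 0.573 and 6.15 ± 0.764 CPM in WT males and females (1.23, SE 0.17, adjusted p = 0.00315), and at 18.2 ± 4.03 and 9.50 ± 1.86 CPM in bsg (0.94, SE 0.14, adjusted p = 0.00833). The totals were 9 genes in WT and 14 in bsg. The numbers moved in both directions of change. The number higher in females was 10 in bsg without bsg male replicate 4, 17 in bsg with library weights, and 13 in WT and 39 in bsg by DESeq2, in place of 6. The number higher in males was 28 in WT and 86 in bsg by DESeq2. In WT it was 7 in place of 3 without WT male replicate 1 and 6 without WT female replicate 4. In bsg it was 2 in place of 8 without bsg male replicate 2, 3 without bsg female replicate 3 or 4, 5 without bsg male replicate 1, 3 or 5 or bsg female replicate 1 or 2, and 0 with libraries summed by title number. The WT total was 14 without WT male replicate 1, 14 without the WT and bsg female replicates 2 and 41 by DESeq2. The bsg total was 9 without bsg female replicate 3, 8 without bsg male replicate 2, 11 without the WT and bsg female replicates 2 and 125 by DESeq2, and upper-quartile scaling split it into 6 higher and 7 lower in place of 8 and 6.

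The last comparison asked whether the genotype difference depended on sex. In the interaction test, 0 of 15013 genes passed by edgeR, with a smallest adjusted p of 0.671. At an unadjusted p under 0.05 there were 776 genes, where 751 are expected with no effect, and DESeq2 and limma-voom also called 0 genes. The median standard error of the interaction on the log2 scale was 0.157. The genes with the smallest p at the required level, none of which passed (adjusted p = 0.888), were MGP_C57BL6NJ_G0032303 on chromosome 7 (24434247 to 24455519, interaction 0.48, SE 0.11) and MGP_C57BL6NJ_G0020836 on chromosome 13 (34106517 to 34135479, 0.38, SE 0.09) with a greater bsg to WT ratio in males. With a smaller ratio in males they were MGP_C57BL6NJ_G0024442 on chromosome 17 (84285823 to 84425218, -0.95, SE 0.21) and MGP_C57BL6NJ_G0034765 on chromosome 8 (132535664 to 132548855, -0.90, SE 0.21).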

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

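The tests of single libraries against their group and of other splits of the samples and the test of group size for the excess in females were set before their results were seen, while the tests of the clustered calls, of the libraries that lie apart, of the shared spread and of the interaction as a reason for the excess in females were chosen only after the results were seen. Of 63 sets of values (library measures and levels of the named genes in groups of 4 or 5), 8 held a library whose gap to the nearest other was large for the range of its group. Chance gives about 1 such set in 20. WT female replicate 2 had 20118 detected genes, where the other 3 had 19055 to 19117, and bsg female replicate 2 had 20589, where the other 4 had 18767 to 19229. The latter library also stood at 74.9 on the first principal component, with the others at -23.4 to 3.56, and at -19.13 on the second, with the others at -13.44 to -11.17. MGP_C57BL6NJ_G0030059 was at 205.6 CPM in WT female replicate 2, below the 234.3 to 239.1 CPM of the other WT females. MGP_C57BL6NJ_G0017218 was at 12.7 CPM in bsg female replicate 1 (the others 8.04 to 9.20) and at 25.3 CPM in bsg male replicate 3 (the others 15.9 to 17.1), and MGP_C57BL6NJ_G0025562 at 17.1 CPM in bsg male replicate 5 (the others 13.6 to 14.5).

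The extra genes detected in WT and bsg female replicates 2 formed a pattern of their own. In both, 22 genes on 11 chromosomes had at least 10 CPM while their median in the other 15 libraries was under 1 CPM, and no other of the 136 pairs of libraries had more than 7 such genes. Together they came to 1743 CPM and 5699 CPM in the 2 libraries, against a median of 10.5 CPM elsewhere and 354 CPM in the next highest library, bsg male replicate 4. Greater depth is argued against as the cause common to both, since bsg female replicate 2 ranked 1 of 17 in total count but WT female replicate 2 ranked 16. The sex of the animals is also argued against as the whole cause. On the first component the other 7 females scored -23.4 to 6.5 (median -10.2). The 8 males scored -31.4 to 29.04, or up to 14.4 without WT male replicate 2, which also lies apart. RNA of another tissue or sample remains a candidate explanation, which the 22 shared genes could reflect, but no marker genes could be tested without names.

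The calls between bsg and WT were denser in 6 bins of 10 Mb on 4 chromosomes than elsewhere (4 bins on 3 chromosomes at 5 Mb). Most calls lay outside these 6 bins, 48 of 82 in males and 224 of 270 in females. The causes weighed here concern the bins only. Reads lost to strain variants in the bsg line would only lower counts. They are argued against as the whole cause, since the 4 bins found in males held 17 of 236 genes called higher in bsg females (7.2%, against 0.9% elsewhere, odds ratio 8.54, interval 4.75 to 14.5, two-sided Fisher's exact test p = 2.08e-10). Reads lost to variants in the WT mice would make genes appear higher in bsg, and that was not tested. For the 24 genes called in either sex inside the 6 bins that were lower in bsg, nothing in the tables decides, and reads moved between close copies of a gene were not tested. The libraries that lie apart are also argued against, since 44 calls in females lay inside the bins without them, against 46 with them. DNA segments inherited with the bsg line are a hypothesis that would give the same direction in both sexes, and 100% of the 52 genes had it, but any genotype difference shared by the sexes would give that too. Whether such segments exist was not tested.

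More genes were called in females than in males, 270 against 82. One library fewer in the WT males is argued against as the whole cause, since with 3 of the 4 WT female libraries the median count was 227 (126 to 333). The estimate of the spread shared by all groups may account for the excess: with the groups of each sex fitted alone, the count was 109 in females and 151 in males. A genotype difference that depends on sex stays open, since 0 genes passed the interaction test and that test recovered 32.8% of simulated 1.5-fold changes.

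The real grouping was set against other splits of the same libraries into groups of the same sizes. Of the 56 splits of the males, 1, the real one, gave as many as 82 genes, and the highest other gave 18. In the same way only the real split reached its count for females (1 of 100 drawn splits, 270 genes against 199 at most), for the sexes in WT (1 of 35, 9 genes against 3) and for the sexes in bsg (1 of 100, 14 genes against 3). These are the smallest shares that so many splits can give, so chance is argued against for these counts but not excluded. Libraries that share a title number were split as if independent. The split of the females with 199 calls set WT female replicate 2 and bsg female replicates 1, 2 and 3 apart, and so put both libraries with extra genes on one side. For the interaction the real count was 0, which each of the 100 splits reaches (100 of 100, highest other 2), so the splits say nothing about chance there.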

How the results depend on the processing

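The fits without the libraries that lie apart, the agreement between the sexes under settings other than RLE scaling and the level filter, and the counts inside the bins were chosen only after the results were seen. RLE and upper-quartile scaling, both filters on low counts and limma-voom without and with the title number as a random block (correlation within a number -0.001) left the 5 counts of genes within 1.5 times of their values. DESeq2 gave 232 genes for bsg against WT in males, 542 in females, 41 for the sexes in WT and 125 for the sexes in bsg. Library weights in limma-voom gave 231 in males and 36 for the sexes in bsg. A fold of at least 1.5 left 51 genes in males, 98 in females and 7 for the sexes in bsg, and an adjusted p under 0.01 left 39, 69 and 8, as stricter thresholds must. The compared groups fitted alone gave 151 in males and 109 in females. Summing libraries by title number left 38, 60 and 4, with fewer samples (2 or 3 per group). Without X genes, 3 genes remained for the sexes in WT and 6 for the sexes in bsg. Without the 2 or 3 libraries that lie apart, the sexes in WT gave 14 and 18 genes. The interaction gave 0 genes under each of the 29 alternatives run. The fold of at least 1.5 and the adjusted p under 0.01 only narrow the main calls, so for them a count of 0 was fixed in advance. Leaving out 1 library gave 39 to 68 genes in males, 126 to 333 in females, 9 to 14 for the sexes in WT, 8 to 21 for the sexes in bsg and 0 for the interaction.

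The correlation across genes between the sexes, 0.332 over all, was 0.076 with no filter on low counts, 0.395 by limma-voom without and with the block, 0.439 for genes with an average log2 CPM of at least 1, 0.239 outside the bins, 0.042 without the 3 libraries that lie apart (-0.057 outside the bins) and 0.212 to 0.388 when 1 library was left out. Of 332 values of the 16 named gene results under alternatives, 317 kept direction and call, 15 kept direction and lost the call, and 0 reversed. MGP_C57BL6NJ_G0030950 accounted for 13 of the 15, and the others were MGP_C57BL6NJ_G0022095 and MGP_C57BL6NJ_G0017218 for the sexes in bsg with libraries summed by title number. Calls inside the bins, 5 Mb and 20 Mb bins included, numbered 22 to 54 in males and 23 to 62 in females over all settings. Where no construction is named, the cause was not tested. The planned gene list tests and their alternatives were not run, because the lists could not be matched to IDs, and the interaction was not fitted with libraries summed or with 2 groups alone. No paired analysis was possible because the labels give the groups no shared replicate numbers. Depth limits genes near the floor of 0.163 to 0.222 CPM (3 counts).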

Other observations

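The genes, libraries and summaries given here were picked out only after the data were examined, while the comparisons between genotypes and sexes and the interaction test were planned, and the values carry no explanation. The neighbouring pair on chromosome 5 moved in opposite directions in every heart. All 10 bsg libraries had between 28.5 and 39.5 CPM of MGP_C57BL6NJ_G0030058 and between 4.18 and 6.18 CPM of MGP_C57BL6NJ_G0030059, while all 7 WT libraries had at most 1 count of the former and at least 203.8 CPM of the latter. Both genes lie on the minus strand, and the one that fell has the higher coordinates and so lies upstream in the direction of transcription.

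The 22 genes high in WT and bsg female replicates 2 were also ranked alike in both, with a Spearman's rho of 0.808 across genes, which are not independent replicates. The sum was higher in bsg female replicate 2, as was each gene's level for 21 of the 22. Of these genes, 21 were tested and 0 were called between bsg and WT in females. Deviations from the group means in these libraries correlated at 0.720 over all tested genes, and the highest value among the other pairs of libraries from different groups was 0.531. Summed CPM of the 22 genes was also 164 in bsg male replicate 1 and 43.8 in WT male replicate 2.

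Chromosome 15 and chromosome 1 held the genes higher in males in both genotypes, and 1 further gene on chromosome 8, at 131020980, was called in WT (log2 fold change 0.99, SE 0.12) but not in bsg (0.42, SE 0.10). Its interaction had an unadjusted p of 0.0015 by edgeR, with no gene past adjustment, so a difference between the genotypes was not shown. This gene is singled out after its values were seen.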
